A study of Mus musculus with 2 samples.

How the data were processed

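Processed peak lists of H3K9ac ChIP-seq from mouse lung at embryonic day 15.5 were used, from 2 biological replicates of 1 group. Reads, alignments, signal tracks and control libraries were not used here. Per the file headers and the text files deposited with them, 4 peak lists in narrowPeak format on mm10 (GRCm38) were made by the authors. They comprise 1 list for each replicate with its control, 1 from the pooled alignments of both replicates with both controls, and 1 of replicated peaks derived from the other 3. The peak caller, its version and the rule for a replicated peak are not given in the sources used here. The deposited lists give for each peak a fold, read as the ratio of ChIP over control, and a −log10 p-value and −log10 q-value, all as computed by the authors. In every list the −log10 p was at least 2. These values are not comparable between lists of different depth, and the depth itself is unknown because the lists hold no counts.

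All 25362 replicated peaks on chromosomes 1 to 19, X and Y are intervals of the pooled list. Peaks of both replicates overlap 22437 of them (88.5%), a peak of replicate 1 only overlaps 1305, of replicate 2 only 1443, and of neither 177. Peaks on other scaffolds, 7 in the replicated list, were left out.

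Gene positions came from GENCODE release M21 on GRCm38 and sequence from the GRCm38 reference, the build of the peak lists; all peaks lay within the chromosome lengths. A promoter was any annotated TSS of a protein-coding gene with 1 kb to either side. A gene was marked when peaks in both replicates' own lists overlapped its promoter by at least 1 bp. CpG observed/expected was counted in 500 bp to either side of each TSS, taking the highest value of a gene, and genes were split into 10 deciles.

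The tests, the 31 gene lists and the alternatives were fixed before the data were examined, except where stated. Of 2455 list symbols, 2451 matched the annotation. Lists were compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 31 lists and a threshold of 0.05. As an alternative, list membership was permuted within CpG deciles to give 10000 random lists, called CpG-matched lists, where the smallest two-sided p these can give is 0.0002. Intervals of shares are exact 95% binomial intervals, and the limit for a count of 0 is 3 divided by the total. Widths were taken from replicated peaks merged within 1 kb, for lists with at least 5 genes. The width of a gene was that of the widest domain overlapping any of its promoters. Distal peaks lay more than 2.5 kb from any annotated TSS and within 50 kb of the 5'-most TSS of a gene. Both were given as percentiles among 10000 random lists, called above 97.5 or below 2.5. Positions were shuffled 100 times within chromosomes.

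Genes were named by a rule: a fixed set of 40 anchor genes, per list the 2 marked genes with the highest fold in the lower of both replicates and the first 2 unmarked ones, the 15 genes with the widest domains, and the nearest genes of the 10 distal peaks of highest fold. A subset is printed. For a named gene, the highest peak fold in its promoters is given per replicate.

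Alternatives changed the overlap required, the number of peaks compared, the regions correlated, the peak threshold (−log10 q of at least 2 or −log10 p of at least 5), the promoter window (500 bp or 2 kb, and 500 bp or 2.5 kb for the location of peaks), the TSS used, the peak list, the merging distance (none or 3 kb), the distal distance (20 or 100 kb) and each replicate left out. After the data were seen, 3 alternatives were added: only genes with no TSS of another gene within 2 kb, only replicated peaks overlapped by both replicates, and only distal peaks outside merged domains that reach within 1 kb of a TSS. The functions were tested on simulated data. Overlap calls differed from a direct count in 0 of 1200 intervals. With marking set by CpG decile alone, 0% of lists over 21911 genes were called by CpG matching. All genes of a decile had the same chance there, so the simulation cannot show whether CpG differences within a decile were matched. Random lists were called in 0.0645% of cases by Fisher's test. Lists with members marked at a share of 10% were called lower in 100% of cases by Fisher's test and 83.0% by CpG matching. For widths over 13000 simulated genes, 2.50% of random lists and 80.0% of widened lists were called, and for distal peaks over 20000 simulated genes, 3.00% and 100%. In these width and distal simulations all lists had the same size and genes were independent. The rates need not hold for lists of other sizes or for genes that share domains. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.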

Results

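H3K9ac, acetylation of lysine 9 on histone H3, marks the promoters of active genes. It was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in lung of B6NCrl mouse embryos of mixed sex at embryonic day 15.5, a stage of branching of the airways. The data formed 1 group of 2 biological replicates, pooled from 78 embryos (replicate 1) and 62 embryos (replicate 2). There was no second group, so the comparisons were between the replicates and, within this tissue, between genes and genomic regions. The peak lists held 42444 peaks for replicate 1, 39393 for replicate 2, 51921 for the pooled alignments and 25369 in the authors' replicated list. Median peak widths were 346 bp, 386 bp, 342 bp and 860 bp in the same order. The peak lists carry no read counts, so the sequencing depth behind each peak is unknown. The fold given for a peak is the authors' own value and is not a level comparable between lists. It was used to describe and rank peaks within a list, to correlate the replicates across shared regions, and to choose which marked genes to name.

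The first question was whether the replicates marked the same regions. Of the peaks of replicate 1, 62.3% were overlapped by a peak of replicate 2. Of the peaks of replicate 2, 66.2% were overlapped by a peak of replicate 1. The mean of the 2 shares was 64.2%. Their SD of 2.76 lies between the 2 directions of 1 comparison and is no spread between biological replicates. After 100 shuffles of peak positions within chromosomes the shares were 2.08% ± 0.0770 and 2.23% ± 0.0867 (SD over shuffles). The shared sequence spanned 19.2 Mb, 74.1% of the sequence covered in replicate 1 and 75.7% of that in replicate 2. When the peaks of each replicate were split into 4 equal groups by −log10 p, 100% of the highest group were shared in both replicates, against 23.7% and 25.9% of the lowest. Shared peaks had a median fold of 5.84 in replicate 1 and 5.97 in replicate 2, and unshared peaks 3.10 and 2.98. Peak centres lay within 1 kb of a TSS (transcription start site) for 75.8% of the shared peaks of each replicate, and for 23.7% and 24.3% of the unshared ones. Across 22874 shared regions, peak fold in the replicates had a Spearman correlation of 0.879 and a Pearson correlation of 0.880 on the log2 scale. Regions are not independent replicates, so no p-value was computed.

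**Figure D1:**
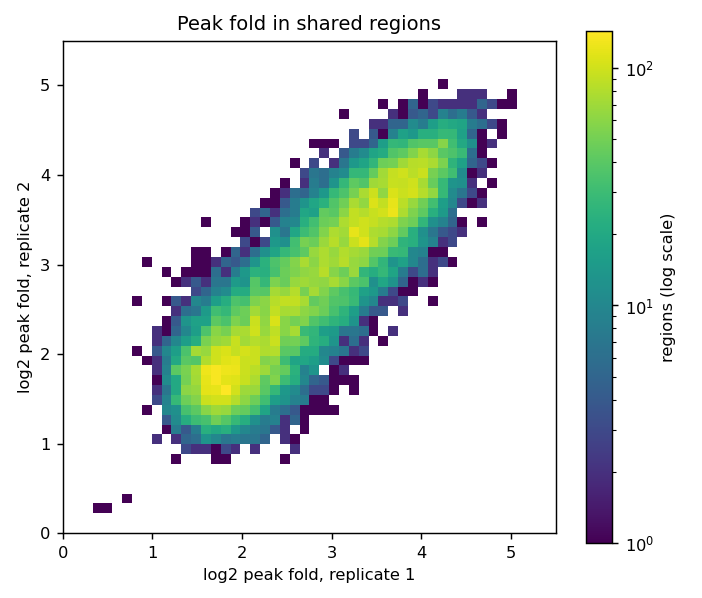
The plot shows the highest log2 peak fold in replicate 1 (horizontal axis) and in replicate 2 (vertical axis) for 22874 regions with a peak in both replicates, coloured by the number of regions per square on a log scale. Both values rise together across regions, with a Spearman correlation of 0.879.

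H3K9ac was concentrated at promoters. In the replicated list, 72.2% of peak centres lay within 1 kb of an annotated TSS, 11.5 times the share in shuffled positions (6.29% ± 0.144, SD over 100 shuffles). Exons held 3.76% of the peaks, introns 13.9% and intergenic sequence 10.1%, against 3.32%, 39.2% and 51.1% after shuffling. In the replicates' own lists the promoter share was lower, at 57.3% ± 1.55 (SD, n = 2), and in the pooled list it was 47.2%. Promoter peaks of the replicated list had a median width of 1058 bp and a median fold of 8.82, while intergenic peaks had 518 bp and 3.84.

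Of 21911 protein-coding genes, 13716 (62.6%) had a peak within 1 kb of a TSS in replicate 1 and 13784 (62.9%) in replicate 2. Both replicates marked 13367 genes (61.0%, exact 95% binomial interval 60.4% to 61.7%), 766 genes were marked in 1 replicate only and 7778 in neither. These intervals cover counting error only. The marked share followed the CpG content of the promoter, as the ratio of observed to expected CpG. It was 0.593% in the lowest decile of CpG content, 41.7% in the fourth, 79.02% in the fifth and 97.1% in the highest. The upper 5 deciles together had 67.0 percentage points more marked promoters than the lower 5.

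**Figure D2:**
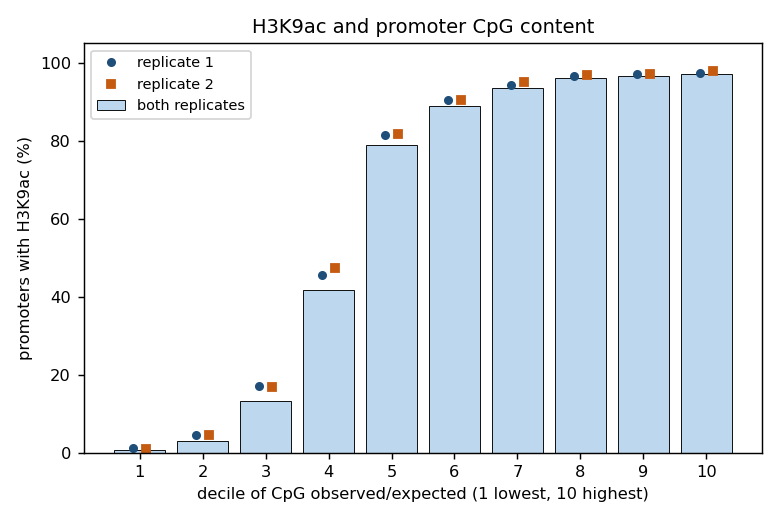
Bars show the percentage of protein-coding promoters with H3K9ac in both replicates for each decile of CpG observed/expected (horizontal axis, 1 lowest), with replicate 1 as circles and replicate 2 as squares. The share climbs from 0.593% in decile 1 to 97.1% in decile 10.

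Epithelial, mesenchymal, smooth muscle and endothelial genes were marked in large part. All 36 genes of the epithelial list were marked, among them Nkx2-1, the regulator of lung identity, the distal tip factors Sox9, Etv5 and Id2, the airway factor Sox2, the signal Shh and the adhesion gene Cdh1. In the mesenchyme and fibroblast list 40 of 42 were marked, including Tbx4, Tbx5, Foxf1, Tcf21 and the growth factor gene Fgf10; Lum, with a peak of fold 2.56 in replicate 2 only, and Nkx2-3, with none, were not. Of smooth muscle and pericyte genes 22 of 24 were marked, including Acta2, and of endothelial genes 32 of 35, including Pecam1, Kdr and Sox17. Pecam1 has the TSS of Milr1 within 2 kb. Nkx2-1, Sox9, Shh, Tbx5, Foxf1, Fgf10 and Sox17 also have a TSS of another annotated gene within 2 kb. Each of these 4 lists exceeded the remaining protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 31 lists, adjusted p = 8.82e-08, 1.43e-06, 0.00172 and 0.000124). Each also exceeded random lists matched on CpG content, whose expected shares were 85.7%, 74.7%, 60.9% and 57.1%. With only peaks of −log10 p of at least 5 the endothelial list no longer passed Fisher's exact test (log2 odds ratio 0.79, adjusted p = 0.144). Genes are not independent replicates, so these p-values describe the lists in this tissue and not a population of embryos.

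Peak fold differed among these marked genes. Nkx2-1 had a highest fold of 11.5 in replicate 1 and 9.39 in replicate 2, and Foxp4, the epithelial gene with the highest lower-of-both fold, had 18.3 and 20.6. Tbx4 had 13.3 and 11.5, and Foxf1 had 14.3 and 12.1. Nr2f2, a gene of the endothelial list, had 20.4 and 19.2, whereas Pecam1 had 3.59 and 3.93 and Sox2 had 3.98 and 5.46. Actb, the cytoplasmic actin gene, had 22.5 and 26.9.

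Differentiated lung lineages were marked in part. Alveolar maturation genes were marked at 17 of 25, including Sftpc, which encodes surfactant protein C (fold 11.8 and 21.5), and Sftpb (2.64 and 3.85). Sftpa1, Sftpd and Aqp5 had no promoter peak in either replicate. Pdpn, Hopx, Ager, Rtkn2, Cav1, Akap5, Clic5 and Emp2, chosen after their values were seen, were marked. Napsa, Lamp3, Lyz2, Cd36 and Sec14l3, chosen likewise, had no peak in either replicate. Sftpc has the TSS of Bmp1 within 2 kb, and both genes share their peak value. Airway genes were marked at 11 of 24: the ciliated cell regulator Foxj1 had a fold of 6.93 and 8.91, Rfx3 and Ccdc40, the latter near the TSS of Tbc1d16, were marked, Scgb3a1 and Scgb3a2 had no peak, and Scgb1a1, the club cell secretoglobin, had a peak of fold 2.89 in replicate 2 only. Neuroendocrine and neuron genes were marked at 9 of 22, with Elavl4 and Phox2a marked and Chga and Chgb not. Ascl1, Calca, Uchl1, Ddc and Ret, chosen after their values were seen, were also marked. Syp, Insm1, Resp18 and Phox2b, chosen likewise, had no peak in either replicate. Mesothelial genes were marked at 7 of 16, and Wt1 had a peak in replicate 2 only. Cartilage genes were marked at 14 of 18. No list of these 5 passed the Fisher test (adjusted p = 0.561, 0.172, 0.0963, 0.230 and 0.250). The neuroendocrine list was lower in Fisher's exact test with promoter windows of 500 bp (adjusted p = 0.0348), with the 5'-most TSS (0.0227), and with −log10 q of at least 2 (0.0190) or −log10 p of at least 5 (0.0213). By permutation within CpG deciles the alveolar list was higher (68.0% against an expected 52.1%, adjusted p = 0.0468) and the neuroendocrine list lower (40.9% against 72.5%, adjusted p = 0.00186). The alveolar value lay near the threshold, and its marked genes include Etv5, which the epithelial list also holds. The samples were labelled as lung, so the cell type that carried a mark is unknown.

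Genes of growth and metabolism were broadly marked. All 40 cell cycle and DNA replication genes were marked, Cdk4 and Ccna2 with the highest fold, and all 26 hypoxia and glycolysis genes, including Gapdh and Vegfa. The signalling pathway list was marked at 64 of 67, the exceptions being Grem1, with a peak of fold 2.76 in replicate 1 only, Aldh1a2, with one of fold 3.47 in replicate 2 only, and Cyp26a1, which was chosen after its values were seen and had none. Cytosolic ribosomal protein genes were marked at 78 of 80, with Rps19 at a fold of 25.2 and 29.2, and oxidative phosphorylation genes at 83 of 88. Replication-dependent histone genes were marked at 57 of 67. All 6 lists exceeded the other genes in the Fisher test, with adjusted p from 1.03e-13 for ribosomal genes to 3.97e-05 for histone genes. By permutation within CpG deciles, of these 6 only the oxidative phosphorylation list stayed higher (94.3% against 85.4%, adjusted p = 0.00186), and the histone list was lower (85.1% against 93.4%, adjusted p = 0.0182). Histone genes include near-identical copies, and how reads shared between copies were treated is not given in the sources used here.

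Genes of other organs were mostly unmarked. Hepatocyte genes were marked at 1 of 32, with Alb and Afp unmarked and only Apoh marked, which has the TSS of Prkca within 2 kb. Pancreas and intestine genes were marked at 1 of 27 (Lgr5), with Pdx1, Ptf1a and Ins1 unmarked. Brain and neuron genes were marked at 8 of 36, with Neurod1 and Neurod2 unmarked, although their CpG content gave an expected share of 82.5%. Pluripotency and germ cell genes were marked at 5 of 29, with Pou5f1 and Nanog unmarked, kidney and gonad genes at 4 of 24, retina and lens genes at 5 of 28. Olfactory receptor genes were marked at 0 of 1092, which allows a share of up to 0.275% by the limit of 3 counts and up to 0.337% by the exact 95% interval. Vomeronasal and taste receptor genes were marked at 2 of 364, Tas1r1 and Vmn1r4, both with the TSS of another gene, Nol9 and Nt5c3, within 2 kb. These 8 lists were lower in the Fisher test, with adjusted p = 2.50e-11 for hepatocyte, 1.70e-09 for pancreas and intestine, 6.36e-06 for brain, 5.52e-06 for pluripotency, 3.08e-05 for kidney and gonad, 9.50e-06 for retina and lens and 2.96e-145 for vomeronasal and taste receptor genes, and a value too small to compute for olfactory receptors. All 8 stayed lower by permutation within CpG deciles, with adjusted p from 0.000775 to 0.0236. Expected shares were 59.4% for pluripotency, 38.6% for kidney and gonad, 38.2% for retina and lens and 34.6% for pancreas and intestine genes. They were 16.9% for hepatocyte, 4.76% for olfactory receptor and 2.21% for vomeronasal and taste receptor genes. All but the expected share of brain genes lay below the 61.0% of all protein-coding genes. The brain share of 22.2% had an exact 95% interval of 10.1% to 39.2%.

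Leukocyte, erythroid, skeletal muscle and keratinocyte genes were also less often marked. The samples were labelled as lung and not as a single cell type. An unmarked gene is therefore not shown to be inactive in every cell type of the lung. Macrophage and leukocyte genes were marked at 5 of 32, Ptprc and Cd68 unmarked and Cd14 and Lcp1 marked, the latter near the TSS of Lrrc63. Erythroid and megakaryocyte genes were marked at 10 of 32: Klf1 and Tfrc were marked, and Gata1 and the beta-globin gene Hbb-bs, which has a near-identical copy, were not. Skeletal muscle genes were marked at 6 of 27, with Myod1 and Myf5 unmarked, and keratinocyte genes at 3 of 26. These 4 lists were lower in the Fisher test (adjusted p = 8.55e-07, 0.00117, 0.000117 and 7.65e-07) and did not pass the permutation within CpG deciles (adjusted p = 0.591, 0.785, 0.153 and 0.533). Among genes with no other TSS within 2 kb, an alternative chosen after seeing the data, the erythroid list no longer passed Fisher's exact test (adjusted p = 0.0770). Cardiac genes were marked at 11 of 26, including Myl4, near the TSS of Cdc27, with Myh6 unmarked, and did not pass Fisher's exact test or the permutation (adjusted p = 0.0883 and 0.749). They were lower in Fisher's exact test under the same 4 alternatives as the neuroendocrine list (adjusted p = 0.0348, 0.00337, 0.00150 and 0.00309). Interferon-induced genes were marked at 14 of 27, with Stat1 and Stat2 marked, the latter near the TSS of Apof, and Isg15 and Ifit1 unmarked. They did not pass Fisher's exact test (adjusted p = 0.354) and were higher by permutation within CpG deciles (51.9% against 33.9%, adjusted p = 0.0350), and lower in Fisher's exact test with −log10 p of at least 5 (adjusted p = 0.0397).

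**Figure D3:**
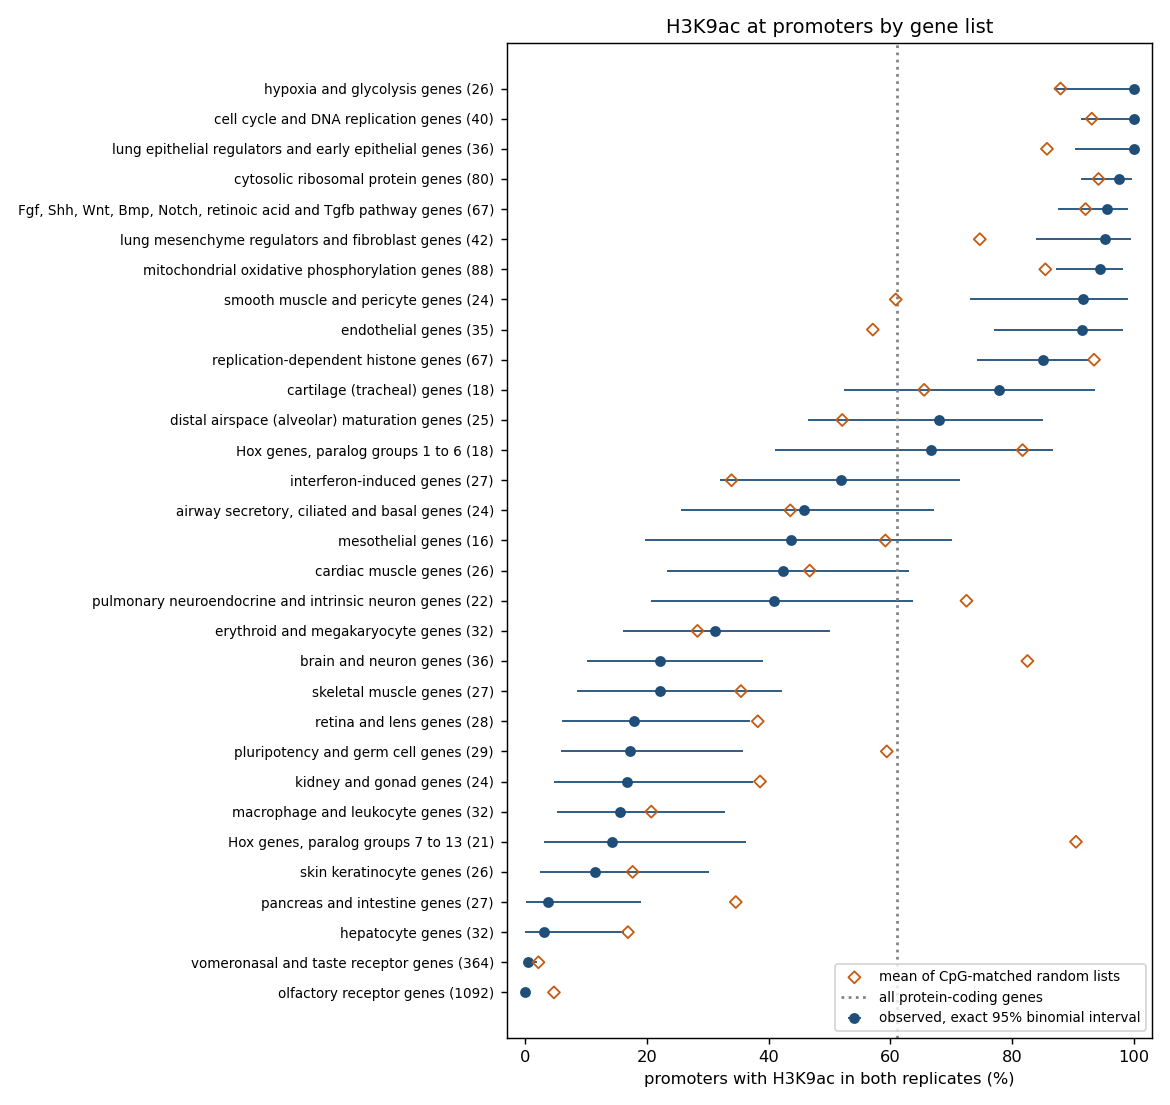
Points show the percentage of promoters with H3K9ac in both replicates for each of 31 gene lists (number of genes in brackets), with exact 95% binomial intervals; diamonds show the mean of CpG-matched random lists and the dotted line the 61.0% of all protein-coding genes. Epithelial, mesenchyme, smooth muscle and endothelial lists lie to the right of their diamonds, and brain genes and Hox paralog groups 7 to 13 far to the left.

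Hox genes, which specify position along the body axis, were marked more often in the lower-numbered paralog groups. Of paralog groups 1 to 6, 12 of 18 genes (66.7%) were marked, against 3 of 21 (14.3%) of groups 7 to 13 (two-sided Fisher's exact test, p = 0.00114). The marked genes of groups 7 to 13 were Hoxa7, Hoxb7 and Hoxb8, the last of which was chosen after its values were seen. HoxA was marked at 6 of 6 genes of groups 1 to 6 and HoxB at 5 of 6, whereas HoxC was marked at 1 of 3 and HoxD at 0 of 3. In groups 7 to 13 the counts were 1 of 5 for HoxA, 2 of 4 for HoxB, 0 of 6 for HoxC and 0 of 6 for HoxD. The clusters were not tested singly, and HoxA held the largest difference. Hoxa5 had a fold of 20.7 and 12.6 and Hoxb5 15.2 and 13.03. Hoxa9, Hoxa10 and Hoxd13 had no peak in either replicate, and Hoxa13 had one of fold 3.47 in replicate 2 only. Replicate 2 alone marked 8 of the 21 genes of groups 7 to 13 and replicate 1 alone marked 3. With replicate 2 alone the difference between the groups had p = 0.0227 (Fisher's exact test). Against all other genes, groups 7 to 13 were lower (adjusted Fisher's exact p = 2.63e-05) and groups 1 to 6 did not differ past the threshold (adjusted p = 0.810); CpG content gave expected shares of 90.4% and 81.7%. In the pooled list groups 7 to 13 no longer passed (adjusted Fisher's exact p = 0.0518). Neighbouring Hox genes share peaks and are not independent.

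**Figure D4:**
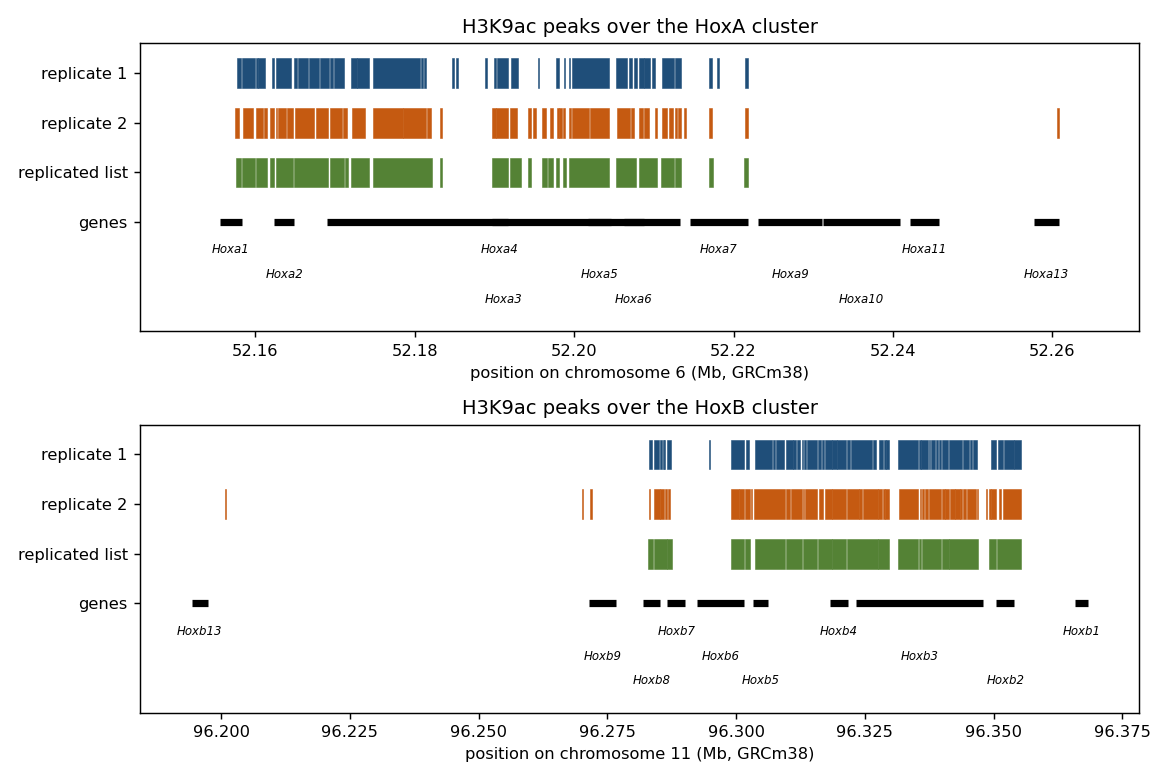
Maps of the HoxA cluster on chromosome 6 and the HoxB cluster on chromosome 11 (horizontal axes, position in Mb, GRCm38) show peaks of each replicate and of the replicated list as boxes, above the Hox genes as black bars. Peaks cover the side of Hoxa1 to Hoxa7 and of Hoxb2 to Hoxb8, and the genes of higher number carry few or none.

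The widest acetylated domains lay over Hox genes. When replicated peaks within 1 kb were merged, 13516 genes had a domain at a TSS. The widest domain at any TSS of a gene was taken, which may lie far from its 5'-most TSS. The median width was 1822 bp (quartiles 1226 to 2546 bp). The widest, of 30645 bp, ran over Hoxb3 to Hoxb6 on chromosome 11 from 96299045 to 96329689 (GRCm38), and the next, of 25850 bp, over Hoxa1 to Hoxa3 on chromosome 6. Nr2f2 had 25742 bp, Nkx2-1 19663 bp (chromosome 12, 56518710 to 56538372), Hoxa5 and Hoxa6 17425 bp, Tbx5 17041 bp and Nfib 16974 bp. In all, 20 domains exceeded 10 kb, also at Bahcc1, Setd1b, Tnrc18, Ctdsp2 and Irf2bp2, which were chosen after their values were seen. No test of the kinds of gene at wide domains was made. Median width was 4150 bp for the epithelial list, 3426 bp for the mesenchyme list, 3618 bp for the pathway list and 25850 bp for Hox groups 1 to 6, each above all 10000 random lists of the same size from genes with a domain. The 12 Hox genes lay in 6 distinct domains, whose median was 11832 bp, also above all random sets of 6 domains. Without merging, the median peak was 2606.5 bp for Hox groups 1 to 6, 2545 bp for epithelial, 2434.5 bp for mesenchyme and 2654.5 bp for pathway genes, against 1413 bp for all genes with a domain. Of 24 lists, 8 were wider and 7 narrower than the central 95% of random lists. The other wider lists were those of ribosomal, cell cycle, histone and hypoxia genes, and histone genes moved to percentile 1.82 when peaks were not merged. Narrower lists included brain and neuron genes (568 bp), airway genes (904 bp) and interferon-induced genes (962 bp), and their number was 11 in replicate 2 alone. The list of smooth muscle genes (1367.5 bp, percentile 2.43) moved to percentile 77.5 in replicate 1 alone, 4.64 in replicate 2 alone, 15.3 without merging, 80.8 when peaks were merged within 3 kb and 95.03 in the pooled list. The narrower call of cartilage genes (percentile 2.30) ended under 5 of 6 alternatives: 28.8 when merged within 3 kb, 21.96 in the pooled list, 9.285 without merging, 8.515 for replicated peaks overlapped by both replicates, an alternative chosen after seeing the data, and 6.065 in replicate 2 alone. That of neuroendocrine genes (1.33) ended at 6.135 without merging. Skeletal muscle genes (percentile 15.3 in the replicated list) were narrower under 5 of the 6 alternatives (percentiles 0.535 to 1.92), retina and lens genes under 3 (0.36 to 1.395), cardiac genes under 2 (0.17 and 2.185), and leukocyte genes (2.40) and erythroid genes (1.14) under 1 each, while alveolar genes were wider when merged within 3 kb (98.34).

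**Figure D5:**
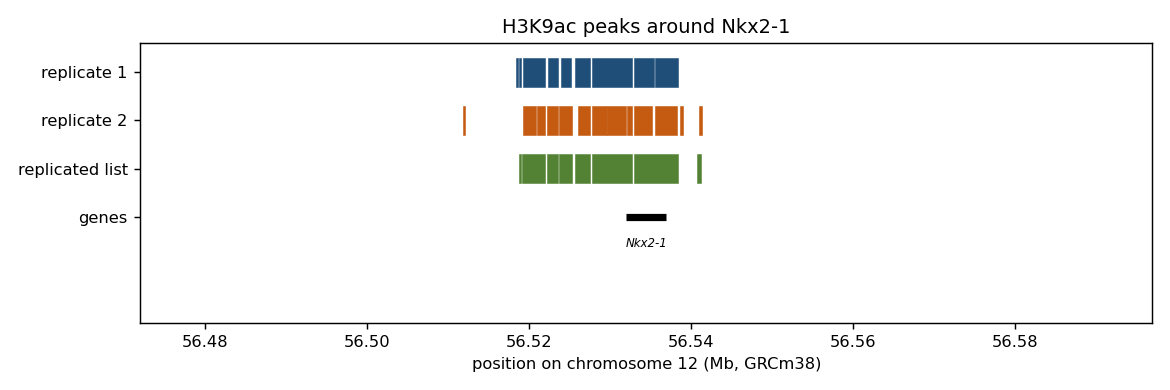
The map of the Nkx2-1 region on chromosome 12 (horizontal axis, position in Mb, GRCm38) shows peaks of each replicate and of the replicated list as boxes above the gene. The merged domain of 19663 bp spans the gene and the sequence beyond its 3' end, and peaks of both replicates lie along it.

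Away from promoters, 4316 replicated peaks (17.0%) lay more than 2.5 kb from any annotated TSS, with a median width of 484.5 bp and a median fold of 3.56. A mean of 0.351 such peaks lay within 50 kb of a protein-coding gene. The mean was 1.33 ± 1.51 (SD over 36 genes) for epithelial genes, 0.952 ± 1.10 (SD over 42 genes) for mesenchyme genes and 1.55 ± 2.49 (SD over 67 genes) for pathway genes. It was 2.27 ± 2.28 (SD over 67 genes) for histone genes, which lie in clusters. Of the 4316 peaks, 264 (6.12%) lay inside a domain, of replicated peaks merged within 1 kb, that reached within 1 kb of an annotated TSS. Of the 5 distal peaks of Nkx2-1 only 1 lay outside such domains, of 4 for Tbx5 2, of 3 for Foxf1 2 and of 5 for Actb 4. Etv5 and Tbx4 had 1 each, outside such domains, Sox9 had 1 inside, and Sox2, Cdh1, Tcf21 and Fgf10 had 0. Of the 31 lists, 8 had more and 2 fewer distal peaks than the central 95% of random lists, the latter being the olfactory and the vomeronasal and taste receptors. Both Hox lists were among the 8 (percentiles 100 and 99.4). Without the peaks inside domains, an alternative chosen after seeing the data, the 2 Hox lists lost their call, their means falling from 2 to 0.0556 for groups 1 to 6 and from 1 to 0.190 for groups 7 to 13 (percentiles 4.83 and 26.03). The other 6 lists kept theirs, with means of 0.972 for epithelial, 0.762 for mesenchyme, 1.22 for pathway and 1.87 for histone genes, against 0.322 for all genes. Hox groups 7 to 13 also moved to percentile 97.34 without replicate 2, 97.09 for replicated peaks overlapped by both replicates, also chosen after seeing the data, 71.9 in the pooled list and 5.68 within 20 kb, and ribosomal genes (98.4) to 85.05 within 20 kb and 97.2 within 100 kb. Other lists gained a call under alternatives: more distal peaks for endothelial genes under 4 of 8 (percentiles 98.05 to 99.92), oxidative phosphorylation genes under 3 (97.98 to 99.66), skeletal muscle genes under 2 (99.26 and 99.7), smooth muscle genes under 2 (98.22 and 98.33) and hypoxia and glycolysis genes under 1 (97.95), and fewer for keratinocyte genes under 3 (0.31 to 2.16). Among the 10 distal peaks of highest fold, the first lay on chromosome 8 from 69716063 to 69716946 in intergenic sequence, 5.78 kb from the nearest protein-coding TSS (Zfp869), with a fold of 26.7. Another, of 4630 bp and fold 24.98, lay on chromosome 15 in an intron of Lncppara, 64.0 kb from Ppara.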

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

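A signal appeared in data that the comparisons do not use. The replicated list held 7 peaks on unplaced or unlocalised scaffolds outside chromosomes 1 to 19, X and Y, and each replicate's own list also held 7. With no control libraries used here, they are given as values. No outlier or difference between groups was looked for, since the design has 1 group of 2 samples.

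The tests below were set before their results were seen, except the CpG test of the 13 lists with fewer marked promoters, which was set afterwards. No biological explanation was tested for any of the 3 patterns, since the design gives no second group.

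Of the peaks of replicate 1, 16002 had no overlapping peak in replicate 2, and 13314 of replicate 2 had none in replicate 1. Weak peaks near the calling threshold are a candidate explanation: of the highest of 4 equal groups of peaks by −log10 p, 0% were missing (mean of both replicates), a share that could have come out higher. Domains cut into different pieces may account for some: 36.7% of the missing peaks lay within 1 kb of a peak of the other replicate, between the bounds set for and against it, so this stays open. A difference in depth was not tested, since the lists hold no counts.

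Of the 13 gene lists with fewer marked promoters by Fisher's exact test, 9 were also lower against lists matched on CpG content, which argues against low CpG content as the whole cause across the 13 lists. The CpG content of brain and neuron genes and of Hox paralog groups 7 to 13 gave expected shares of 82.5% and 90.4%, above the 61.0% of all genes and not below it. The other 4 lists, of leukocyte, erythroid, skeletal muscle and keratinocyte genes, lay on average 5.38 percentage points below their expected share (mean difference -5.38). The single differences were -5.1, 2.94, -13.2 and -6.13 in that order, so the erythroid list lay above its expected share. A test set on the mean difference had favoured low CpG content and was dropped afterwards, because these lists were picked by the same matching. Low CpG content therefore stays open for these 4 lists.

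Domains were wide at Hox paralog groups 1 to 6 and at epithelial, mesenchyme and pathway genes. With single unmerged peaks the lowest percentile of the 4 lists was 99.98, which argues against merging as the whole cause, but the Hox median fell from 25850 bp to 2606.5 bp and the epithelial one from 4150 bp to 2545 bp (all genes 1413 bp), so merging sets much of the size. Against lists matched on the number of annotated TSSs within 15 kb of the 5'-most TSS, the lowest percentile was 100. It was also 100 against lists matched on CpG content. This argues against TSSs crowded around the 5'-most TSS, and against CpG content, as the whole cause. Each gene was given the widest domain at any of its TSSs. TSSs of a gene farther away were not matched, so their number stays open as a cause. The percentiles treat genes as separate, while the 12 Hox genes share 6 domains. That these 4 lists carry wide domains beyond these effects remains a hypothesis, found and tested on the same data.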

How the results depend on the processing

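The Hox difference stayed past its threshold under the 9 alternatives run. The number of lists with higher marked shares was 7 to 10 and with lower 11 to 16; under CpG matching 5 of the 10 higher and 9 of the 13 lower lists kept their call. Values with no test were compared with the SD between the replicates. For the replicate overlap this was the SD between the directions of the comparison, and for the correlation a bootstrap interval across regions. Leaving out a replicate can only add marked genes, since a gene had to be marked in both. For location, width and distal results it meant using the other replicate's own list in place of the replicated list. The kind of list changes with it, so such a shift cannot be put down to the replicate left out. The causes of the shifts were not tested. Depth is unknown, so weak peaks missing from a list may lie below its detection limit: the overlap of replicates was 72.95% with −log10 q of at least 2 and 78.7% with −log10 p of at least 5, against 56.5% and 47.4% when 50% of the peak or reciprocal 50% was required.

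The rank correlation was 0.870 in promoter regions and 0.8685 with −log10 q of at least 2. The promoter share of peaks was 47.2% in the pooled list, and 82.0% and 55.5% within 2.5 kb and 500 bp. It was 74.0% with −log10 p of at least 5 and 56.2% to 58.4% in a single replicate's own list. Replicated peaks overlapped by both replicates had 76.9%. The marked share of genes was 60.3% and 61.8% with TSS windows of 500 bp and 2 kb, 57.1% with the 5'-most TSS, 61.7% and 65.3% with the replicated and pooled lists, 59.5% and 58.4% with the stricter q and p, 62.6% to 62.9% without one replicate and 51.15% for genes with no other TSS within 2 kb. For the same settings apart from the last, the CpG difference was 67.7, 65.8, 64.8, 66.7, 62.7, 68.1, 69.0 and 65.2 to 65.3 percentage points. The number of narrower lists was 9 to 11 in a single replicate's own list.

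Against CpG-matched lists the log2 odds ratio turned to 0.13 for airway, 0.19 for erythroid and -1.06 for Hox groups 1 to 6. These did not pass the permutation (adjusted p = 0.968, 0.785 and 0.175). It also turned to -1.23 for histone and 1.03 for interferon-induced genes. This ratio sets a list against its own expected share, while the main one sets it against other genes. With the 5'-most TSS the main ratio turned to -0.11 for Hox groups 1 to 6, which did not pass Fisher's exact test. The width percentile of smooth muscle genes, 2.43, turned to 80.8 when merged within 3 kb, 95.03 in the pooled list and 77.5 without replicate 2. It was 4.64 without replicate 1, still on the narrow side but no longer called. That of histone genes, 100, turned to 1.82 with no merging. The distal percentile of Hox groups 7 to 13, 99.4, turned to 5.68 within 20 kb and 26.03 for peaks outside domains at a TSS, and that of Hox groups 1 to 6, 100, to 4.83 for the same peaks. Of 341 list results under alternatives, 314 kept their direction and side of the threshold, 11 newly passed it, 10 no longer passed it and 6 turned. Of 144 width percentiles under alternatives, 119 kept their call, 8 lost it, 13 gained one and 4 turned. Of 248 distal percentiles 225 kept it, 5 lost it, 15 gained one and 3 turned. A list result turned when its sign changed, and a called percentile when it crossed the middle of the random lists. Only that of histone genes with no merging was then called on the other side. The other turned percentiles lost their call too, and are not among those counted as lost. Of the 164 named genes, the marking call was the same in 1427 results under alternatives, gained in 32 and lost in 17. The genes with no other TSS within 2 kb, the replicated peaks overlapped by both replicates and the distal peaks outside domains were chosen after seeing the data.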

Other observations

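Promoters of other gene types were counted with no test of the difference and no matching on CpG content. Of 5854 lincRNA genes 652 (11.1%) were marked in both replicates, of 2959 antisense genes 911 (30.8%) and of 9940 processed pseudogenes 88 (0.885%). Away from protein-coding promoters the shares were 6.04% of 5367 lincRNA genes, 7.01% of 1655 antisense genes and 0.581% of 9635 processed pseudogenes.

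The tests that follow were set before their results were seen. X-linked promoters were marked at 398 of 948 genes (41.98%), against 62.4% of autosomal promoters. Random autosomal lists matched on CpG decile had a mean of 48.5% and a central range of 46.4% to 50.5% (two-sided permutation p = 0.0002, the smallest that 10000 lists can give). The X chromosome holds multicopy gene families in which reads may be shared between copies, which was not tested for this share of 41.98%.

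Domains at 2283 genes in divergent pairs, with protein-coding TSSs within 1 kb of each other, had a median width of 2344 bp, against 1902 bp in CpG-matched random lists (percentile 100). Merging within 1 kb can itself join the peaks of a pair, so single unmerged peaks were compared in a test added after the merged widths were seen. Their median was 1638 bp against 1478 bp (percentile 100), which argues against merging as the whole cause of the difference. A peak that spans both TSSs of a pair may still account for it, which was not tested. Paired genes share a domain, so the genes are not separate observations. Zinc finger genes named Zfp were marked at 334 of 394, and their domains had a median width of 1527 bp against 1614 bp in CpG-matched lists, at percentile 6.37, inside the central range of random lists; the hypothesis of narrower domains was not borne out at the bound set.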
